A study of Mus musculus with 6 samples.

How the data were processed

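The series held 6 samples of mouse lung cells, 3 of cells sorted for Muc1 and Pdpn at embryonic day 18 and 3 of adult cells sorted for Lyz2 and EpCAM, each described as a biological replicate. Per the labels' protocols, total RNA was extracted with a column kit for small samples, amplified in 2 cycles of cDNA synthesis, labelled with biotin and hybridized to an Affymetrix whole-genome mouse 3' expression array, 1 per sample. Whether animals were pooled for a sample, and their sex, was not given in the sources used here. Grouping followed the labels, with 2 groups of 3, and no sample was left out.

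The deposited values were linear signal intensity per probe set, produced with Affymetrix Expression Console and MAS5 per the submitters' processing notes. The values themselves showed the scaling that had been applied, since the trimmed mean of each array, without the lowest and highest 2% of values, was 500.003 or 500.004. All values were above 0, so they were log2 transformed here with no pseudocount and no further normalization. The arrays were checked for copied data, and the highest share of identical values between a pair of arrays was 0.00222%.

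Of 45101 probe sets, 64 were controls, 34945 were paired with exactly 1 gene symbol, 932 with several and 9160 were not listed in the array's gene table. Gene names came from that table, 34741 probe sets matched a RefSeq gene table of the mouse assembly GRCm38.p6 by gene ID, and 0 symbols needed an update. The assembly was used for names only, and no coordinates are given. For each of 18193 genes the probe set with the highest mean log2 signal over all arrays was used. A gene was tested if its probe set reached its array's 40th percentile of all probe sets, used as the detection floor, on at least 3 of the 6 arrays, which kept 13335 genes and removed 4858. The floor lay at signals of 53.6, 50.2 and 68.6 in E18 replicates 1, 2 and 3 and 55.9, 42.3 and 66.5 in adult replicates 1, 2 and 3. It marks a rank within the array and not a measured background, and the precision is limited by the number of arrays.

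Groups were compared with limma 3.58.1 in R 4.3.3, with a linear model per gene, an intensity trend in the variance prior, and Benjamini-Hochberg adjustment over the genes tested. Every adjusted p for a gene is from this two-sided test, and SE is its moderated standard error. The median residual SD was 0.53 and the prior had 3.59 degrees of freedom. For genes whose lower group was under the floor in all 3 arrays, the fold was computed against the floor and is given as "at least". Lists of genes were tested with limma's camera with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 35 of 36 lists with at least 5 genes tested. Camera compares a list with all other genes, so it was repeated with the correlation estimated from the arrays, and limma's fry was run in its directional form. Array control measures were compared by exact two-sided permutation tests. Similarity between arrays is Pearson's correlation across genes, a description with no test.

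The groups, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The 36 lists held 937 entries, 868 of which matched a gene on the array, and covered the sort genes, alveolar type I and type II cells, cell division, lipid and cholesterol synthesis, lysosomes, MHC class I and class II, innate defence, interferon response, fetal growth, lung transcription factors, EGF receptor, FGF, Wnt, Notch and YAP signalling, basement membrane, glycogen, glycolysis, respiratory chain, ribosome, ion transport, antioxidant enzymes, stress, club, ciliated and basal airway cells, macrophages, leukocytes, endothelium, mesenchyme, mesothelium, erythroid cells and epithelium. The lists were compiled from general knowledge of marker genes and pathways, and some genes belong to more than 1 list.

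Genes were named by a fixed rule. It took the 6 largest folds per direction among genes at an adjusted p under 0.05, at least 2-fold, and with arrays of the groups not overlapping, whose lower group was at or above the floor. It added the 4 brightest genes per direction whose lower group was under the floor on all 3 arrays, the 4 sort genes, and up to 4 members per list that passed, in order of size, or the brightest members up to 2 where fewer than 2 passed. Predicted clones were left out of the first parts. Genes named outside this rule are said to be chosen after their values were seen.

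The steps were tested on simulated data drawn with the means and residual SDs of the 13335 genes, with 200 genes changed by known amounts. Of these, 2% were called at a log2 size of 1, 22% at 2, 84% at 4 and 92% at 6, and of 106 calls 6 were false. A shifted simulated list had a camera adjusted p of 1.09e-29 and an unshifted list one of 0.30. The draw used the mean and SD of each gene and no correlation between genes. It therefore does not show how often camera passes unshifted lists of correlated genes. In the arrays the estimated correlation within a list reached 0.88. Splits of the arrays other than the real one passed 10 to 18 lists, with 0 genes changed. Those splits mix the groups unevenly and keep part of their difference, so they give no rate for unshifted lists either.

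The alternatives fixed in advance were quantile normalization across arrays, centring each array on its median, no filter and a filter at the 60th percentile, values under the floor set to it, addition of 32 before the log, a variance prior without trend or with robust estimation, the mean of a gene's probe sets, omission of less specific probe sets where the gene had another, testing of all probe sets, a replicate block, omission of each replicate in turn, and lists without the sort genes. Alternatives chosen after seeing the data were a block for the poly-A spike-in batch, replicates 1 and 2 alone, replicate 3 alone as values with no test, and E18 replicates 1 and 2 averaged and counted as 1 sample. Array quality came from the 3' and 5' control probe sets of Gapdh and Actb and from 24 poly-A and 18 hybridization spike-in probe sets. Figures were drawn with matplotlib 3.10.9. Probe sets paired with several genes were not tested.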

Results

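Gene expression was measured in 2 populations of mouse lung cells purified by fluorescence-activated sorting, with 3 labelled biological replicates of each and 1 Affymetrix whole-genome mouse 3' expression array per replicate. The E18 samples were cells bearing Muc1 and Pdpn from lungs at embryonic day 18, which the series calls bipotent progenitors, the fetal cells that give rise to alveolar type I and type II cells. The adult samples were cells carrying Lyz2 and EpCAM, which the series calls alveolar type II cells, the surfactant-secreting cells of the alveolus. The series was made to compare expression between these populations, and age and cell population differ together. After the authors' scaling the median probe set signal per array was 92.3, 87.2 and 112 in E18 replicates 1, 2 and 3, and 85.5, 70.2 and 110 in adult replicates 1, 2 and 3. Arrays give no counting depth, and their number limits the precision. Differences are on the log2 scale, adult minus E18, so that negative values are lower in the adult arrays.

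Lists of mesenchymal, endothelial and mesothelial genes and of basement membrane, fetal growth, type I cell and cell division genes were lower in the adult samples, with medians from -3.76 for mesenchymal to -1.75 for cell division genes. MHC class II genes, with a median of 3.34, and leukocyte genes, with 1.13, were higher. H2-Ab1, a chain of the MHC class II molecule, was higher in the adult arrays by a log2 difference of 4.25 (14.02 ± 0.27 against 9.77 ± 0.21, mean log2 ± SD, n = 3). Col4a2, a basement membrane collagen chain, was 19.6-fold lower (8.33 ± 0.54 against 12.62 ± 0.17), and Akap5, a type I cell marker, was 25.9-fold lower (7.87 ± 0.96 against 12.56 ± 0.29). Lyz2, the lysozyme gene named in the adult sort, was 7.27-fold lower in the adult arrays. Of 35 gene lists large enough to test, 14 shifted lower and 9 shifted higher in the adult arrays by limma's camera with a preset correlation of 0.01 between genes. With the correlation estimated from these arrays 0 lists passed and the lowest adjusted p was 0.256, while limma's fry, which asks only whether a list's genes move 1 way, passed 13 lists, 11 lower and 2 higher. Adult replicate 3 differed from the other adult arrays in its airway, epithelial and leukocyte genes, which is given beside each group it touched.

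Of 13335 genes tested with limma, 798 changed at an adjusted p under 0.05, 188 higher and 610 lower in the adult arrays, and each of the 798 changed at least 2-fold. The share lower was 76.4%, and it was 70.8% after quantile normalization and 71.7% with arrays centred on their medians. The median difference over all genes was -0.17, and it was -0.05 and -0.02 under those scalings. At an unadjusted p under 0.05 there were 2883 genes, 21.6% of those tested. The arrays of the groups did not overlap for 28.9% of genes, where chance gives 10%. The lower group was under the detection floor for 144 of the 798 genes, 36 of them higher and 108 lower in the adult arrays.

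Which replicates entered the comparison moved the count more than any other choice. It was 572 without adult replicate 1, 226 without adult replicate 2, 2770 without adult replicate 3, 69 without E18 replicate 1, 66 without E18 replicate 2 and 505 without E18 replicate 3. E18 replicates 1 and 2 were the closest arrays, with a correlation of 0.983 across genes, and with their average counted as 1 sample 63 genes changed. The third replicates of both groups carried far higher poly-A spike-in signals, so this apparent batch, which no label names, was also examined after the data were seen. With the batch as a block 897 genes changed, and in replicates 1 and 2 alone 2996 did, while replicate 3 alone is 1 array against 1 and has no test. Correlations across genes, which are not independent replicates, were 0.921 to 0.983 among E18 arrays, 0.777 to 0.913 among adult arrays and 0.761 to 0.841 between groups.

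**Figure D1:**
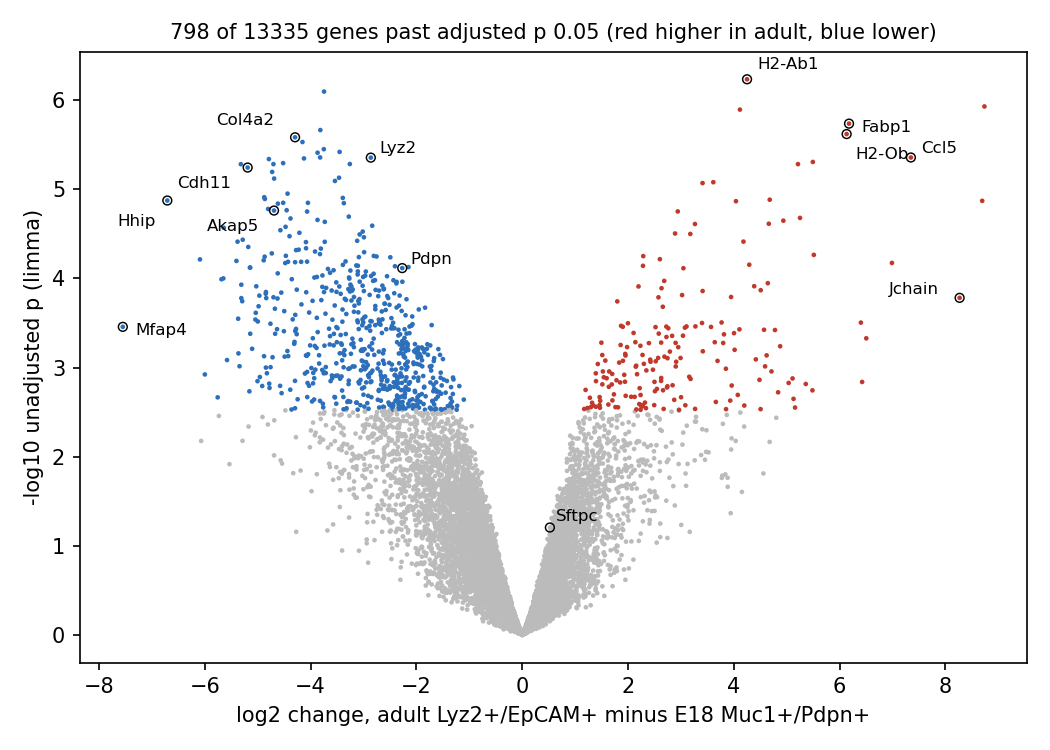
Each point is 1 of the 13335 genes tested, with the log2 difference, adult minus E18, on the x axis and the negative log10 of the unadjusted p on the y axis. Coloured points are the 798 genes past an adjusted p of 0.05, 610 of them lower in the adult arrays, and named points include H2-Ab1, Lyz2, Col4a2 and Akap5.

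Among genes whose E18 mean was at or above the floor and whose arrays did not overlap between groups, the 6 largest increases were in Jchain, Ccl5, Igha, H2-Ob, Klrd1 and Icos. Jchain, the joining chain of secreted antibodies, was higher by 8.27 (SE 1.20, adjusted p = 0.0118), or 176-fold with values under the floor set to it, and Igha, an antibody heavy chain, was 90.7-fold higher (6.50, SE 1.11, adjusted p = 0.0198). Jchain stood at 4.08, 4.89 and 9.28 in E18 replicates 1, 2 and 3, under the floor in replicates 1 and 2. The chemokine Ccl5 was 163-fold higher (7.35, SE 0.64, adjusted p = 0.00303), Klrd1, a receptor of natural killer cells, 45.1-fold (5.49, SE 0.48, adjusted p = 0.00303), and the T cell costimulator Icos 41.1-fold (5.36, SE 1.11, adjusted p = 0.0346). H2-Ob, a chain of the class II chaperone H2-O, was 70.1-fold higher (6.13, SE 0.49, adjusted p = 0.00303). Among genes under the floor in all E18 arrays, Fabp1, a fatty acid binding protein, was at least 45.2-fold higher, Iglv1 at least 32.5-fold, Ifi202b at least 23.1-fold and Ctsw at least 15.7-fold. Immunoglobulin, MHC and Ifi200 family members have near-identical relatives, so probe sets for Igha, Iglv1, Ifi202b, H2-Ab1 and H2-Ob may not be specific to 1 gene. Signals in adult replicate 3 were lower than in the other adult arrays for Klrd1 (11.10 against 12.88 and 12.54) and Icos (9.17 against 14.18 and 12.22), but not for Jchain (14.66 against 14.17 and 14.22).

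Under the same limits on the adult mean and overlap, the 6 largest decreases were in Rian, Col5a2, Cdh11, Lox, Fstl1 and Col1a1. Of the named genes, Mfap4, Hhip and Krt15, given below, had larger measured differences than any of these, with adult means under the floor. Rian, an imprinted noncoding RNA, was lower by a log2 difference of -5.65 (SE 0.76, adjusted p = 0.0103). The collagen genes Col5a2 (-5.40, SE 0.68, adjusted p = 0.00895) and Col1a1 (-5.14, SE 0.86, adjusted p = 0.0184), the collagen crosslinking enzyme Lox (-5.18, SE 0.62, adjusted p = 0.0081), the mesenchymal cadherin Cdh11 (-5.19, SE 0.47, adjusted p = 0.00317) and the secreted glycoprotein Fstl1 (-5.14, SE 0.67, adjusted p = 0.00924) fell by similar amounts. Among genes under the floor in all adult arrays, the hedgehog antagonist Hhip was at least 30.8-fold lower, the transcription factor Mycn at least 11.5-fold, Armcx4 at least 11.4-fold and the matrix protein Egflam at least 11.3-fold.

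Single-gene calls depended on which of the 6 arrays were included. Across this account 112 genes are named by the rule fixed in advance, and 90 of them passed. Leaving out 1 array ended 22 of these 90 calls for adult replicate 1, 47 for adult replicate 2, 0 for adult replicate 3, 67 for E18 replicate 1, 69 for E18 replicate 2 and 27 for E18 replicate 3, with no reversal of direction. The 21 genes that passed in every such fit and every other setting run were Ccl5, H2-Ob, Klrd1, Fabp1, Iglv1, Ifi202b, Cdh11, Hhip, Egflam, Lyz2, Akap5, Col4a4, Agrn, H2-Ab1, Cd74, H2-Eb1, Nlrc5, Fzd2, Tgfb2, Npnt and Col4a2. The lower group was under the floor on all 3 arrays for 16 of the 90 genes, on 2 arrays for 6 and on 1 array for 12. With values under the floor set to it, the differences of those 6 were 7.46 for Jchain, -5.44 for Rian, -3.06 for Fgfr4, 4.14 for Cd2, -5.81 for Mfap4 and -4.53 for Mfap2, and Tie1, Wt1 and Cldn6 no longer passed (adjusted p = 0.0801, 0.0584 and 0.0811). Of the named genes, 52 had more than 1 probe set above the floor, and for 9 of these the probe sets differed in sign, which were Csf1r, Elovl5, Hmgcs1, Idi1, Notch2, Npc2, Pgk1, Rps20 and Sox4.

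The genes whose products defined the sorts were examined first as a check of the labels. Lyz2 was bright in all arrays and lower in the adult arrays sorted for it, at 11.28 ± 0.15 against 14.15 ± 0.12 (SD, n = 3), a difference of -2.86 (SE 0.25, adjusted p = 0.00303). The difference was -2.73 in replicates 1 and 2 alone (adjusted p = 0.0056) and -3.14 in replicate 3. Pdpn, a surface glycoprotein of type I cells and a marker of the E18 sort, was 4.82-fold lower in the adult arrays, at 9.69 ± 0.27 against 11.96 ± 0.27 (adjusted p = 0.00924). Its adjusted p was 0.0582 without E18 replicate 1 and 0.0747 without E18 replicate 2, and its difference was -2.30 in replicates 1 and 2 alone and -2.20 in replicate 3. Muc1, the mucin of the E18 sort, did not pass (9.53 ± 1.85 against 11.60 ± 0.44, adjusted p = 0.206), and neither did Epcam, the epithelial adhesion molecule of the adult sort (9.01 ± 1.48 against 10.42 ± 1.05, difference -1.41, adjusted p = 0.359). In adult replicates 1, 2 and 3 Muc1 stood at 7.92, 9.14 and 11.5 and Epcam at 7.85, 8.50 and 10.7. Without adult replicate 3 the difference of Muc1 was -3.07 (adjusted p = 0.00546) and that of Epcam -2.24 (adjusted p = 0.0382), whereas without adult replicate 1 they were -1.26 and -0.83 and within replicate 3 they were 0.45 and 1.42. In this list of 4 genes 2 were lower, 0 higher and 2 did not pass, with the same counts adjusted over the list alone and a median of -2.17. The list is too small for the set test, and its genes were used to choose the cells.

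**Figure D2:**
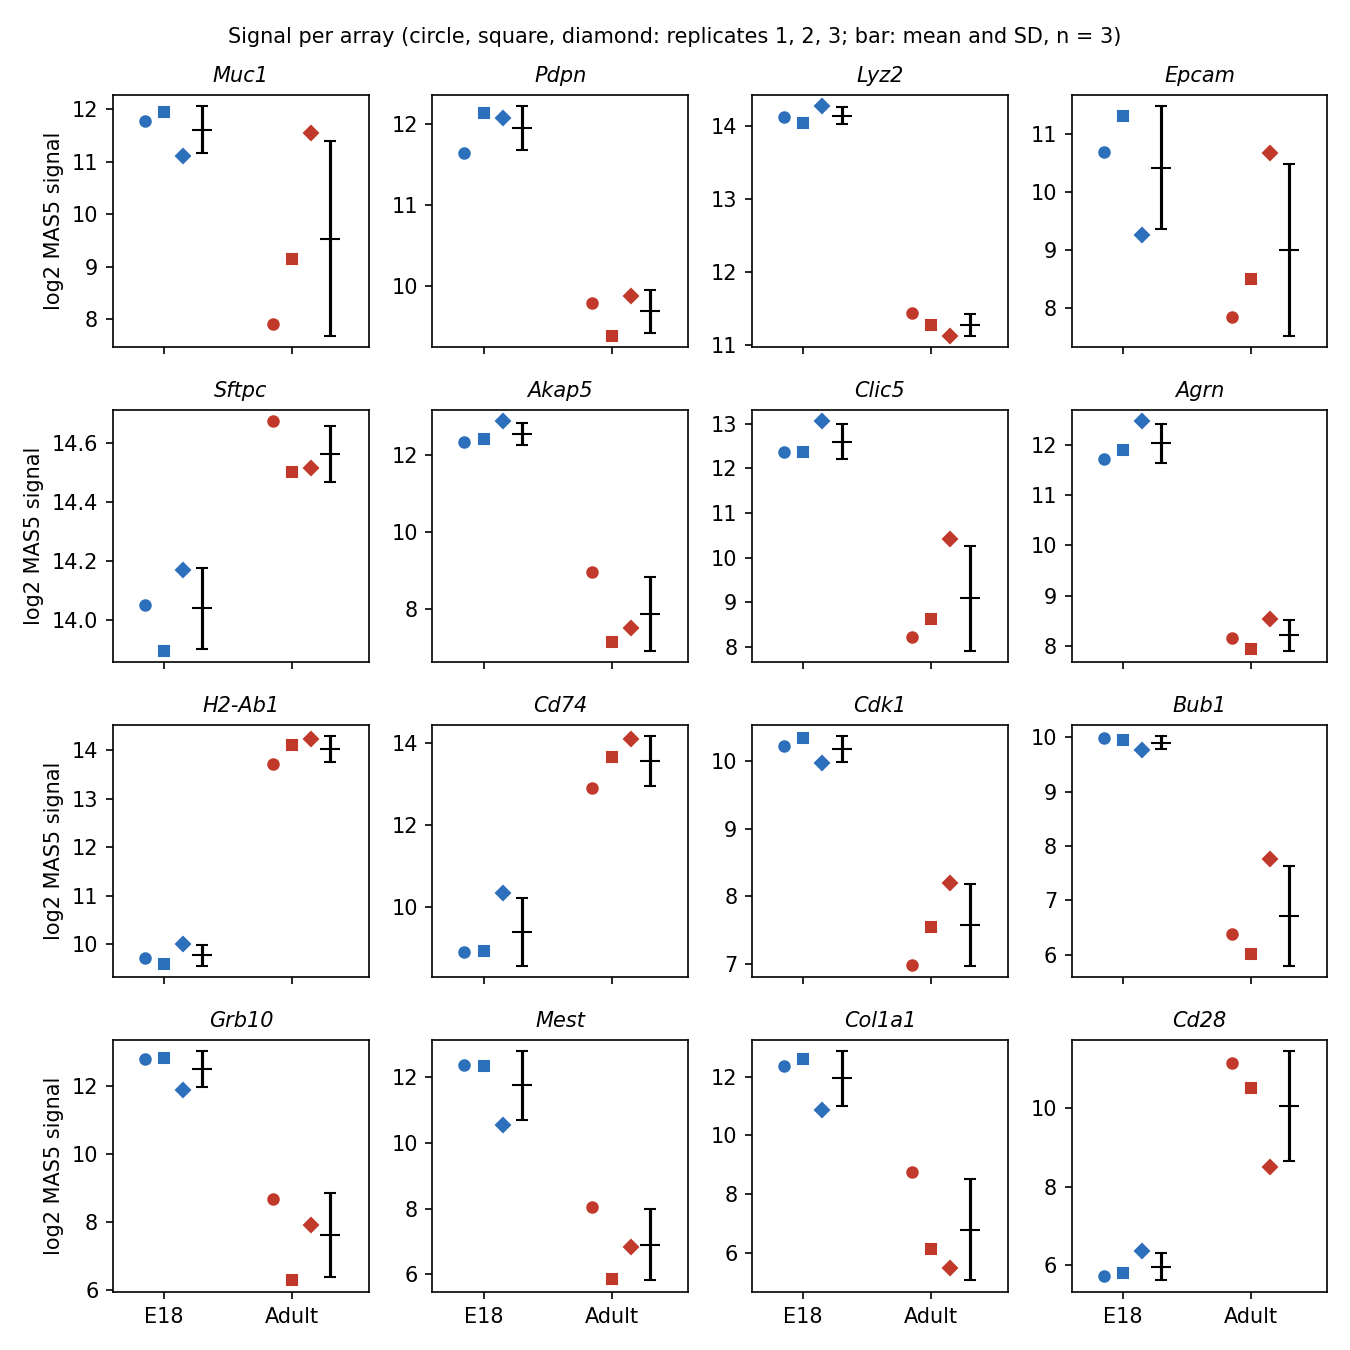
Log2 signal per array for 16 genes, the sort genes and examples from the lists, in E18 and adult arrays. Circles, squares and diamonds are replicates 1, 2 and 3, and bars are the mean and SD (n = 3). Lyz2 lay above 14 in the E18 arrays and below 11.5 in the adult arrays, and Muc1 and Epcam were highest among adult arrays in replicate 3.

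Type I cell genes were lower in the adult arrays, while type II cell genes as a group did not pass. Of 27 type I genes 12 fell, 0 rose and 15 did not pass, with a median of -2.61 (camera adjusted p = 1.24e-09, adjusted p = 0.273 with an estimated correlation). Adjusted over the list alone, 21 were lower and 2 higher. Mesenchymal, endothelial and mesothelial lists fell in the same arrays, by medians of -3.76, -2.85 and -2.25, as did the general epithelial list, by -1.61. Besides Akap5 (-4.69, SE 0.49, adjusted p = 0.00504), the largest decreases were in the kidney and alveolar collagen chain Col4a4 (-3.92, SE 0.48, adjusted p = 0.00853), the heparan sulfate proteoglycan Agrn (-3.82, SE 0.33, adjusted p = 0.00303) and the chloride channel protein Clic5 (-3.51, SE 0.57, adjusted p = 0.0171). The median was -2.56 in replicates 1 and 2 and -1.69 in replicate 3. Col4a3, Col4a4 and Agrn also belong to the basement membrane list, Clic5 also to ion transport, and Pdpn was used in the sort. Ager, the type I receptor chosen for mention after its values were seen, was 12.75 ± 0.71 against 14.11 ± 0.25 (-1.36, adjusted p = 0.0949).

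Surfactant protein transcripts were bright in both populations, and whether differences between signals this bright were compressed was not tested. Sftpc, the surfactant protein specific to type II cells, stood at 14.56 ± 0.10 in the adult arrays and 14.04 ± 0.14 in the E18 arrays (0.52, adjusted p = 0.258), and the difference for Sftpb was -0.05 (adjusted p = 0.965), both chosen after their values were seen. Of 24 type II genes 2 fell, Lyz2 and Egfl6 (-2.28, SE 0.53, adjusted p = 0.0495), 0 rose and 22 did not pass, and the counts adjusted over the list alone were also 2 lower and 0 higher. The list's median was -0.44 (camera adjusted p = 0.30, adjusted p = 0.736 with an estimated correlation). It was -0.95 in replicates 1 and 2 (adjusted p = 0.0237) and 0.52 in replicate 3. The list passed without E18 replicate 3 (-0.78, adjusted p = 0.0144), after quantile normalization (-0.54, adjusted p = 0.00591) and with probe sets averaged (-0.63, adjusted p = 0.0480). Lyz2 and Muc1 in this list were used in the sorts.

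MHC class II genes rose together in the adult arrays, with the highest median of the 35 lists. Of 10 genes 8 rose, 0 fell and 2 did not pass, and adjusted over the list alone 9 were higher. The median was 3.34 (camera adjusted p = 9.43e-15, adjusted p = 0.256 with an estimated correlation). Besides H2-Ob, H2-Ab1 rose by 4.25 (SE 0.28, adjusted p = 0.00303), Cd74, the invariant chain, by 4.18 (SE 0.49, adjusted p = 0.00725) and H2-Eb1 by 3.61 (SE 0.34, adjusted p = 0.00378). The increase was present in both sets of replicates split by poly-A signal, with a median of 3.53 in replicates 1 and 2 and 2.88 in replicate 3. The leukocyte list moved the same way in replicates 1 and 2, where its median was 2.11, but not in replicate 3, where it was -0.13. Dendritic and plasma cell lists, compiled after the data were seen, were higher in the adult arrays by medians of 3.96 and 4.11, and adult replicate 3 differed from adult replicates 1 and 2 by 2.55 and 0.31 for these lists.

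The MHC class I and interferon response lists shifted higher by smaller amounts. Of 12 class I genes 5 rose, 0 fell and 7 did not pass, with 8 higher when adjusted over the list alone and a median of 0.93 (camera adjusted p = 2.51e-08, adjusted p = 0.256 with an estimated correlation). Nlrc5, a transcriptional activator of class I genes, rose by 2.94 (SE 0.31, adjusted p = 0.00504), the peptide transporter Tap1 by 2.00 (SE 0.32, adjusted p = 0.0167), and the immunoproteasome subunits Psmb9 and Psmb8 by 1.98 (adjusted p = 0.022) and 1.64 (adjusted p = 0.0297). The median was 1.00 in replicates 1 and 2, 0.81 in replicate 3 and 0.48 after quantile normalization. Of 25 interferon response genes 2 rose, Cxcl9 (at least 4.03-fold, adjusted p = 0.0277) and Gbp2 (2.30, SE 0.44, adjusted p = 0.0268), 0 fell and 23 did not pass, with the same counts adjusted over the list alone. The list's median was 0.37 (camera adjusted p = 0.00322, adjusted p = 0.459 with an estimated correlation). It was 0.72 in replicates 1 and 2 and -0.43 in replicate 3, and without adult replicate 2 it was 0.26 (adjusted p = 0.128). As departures from each gene's mean, its medians in adult replicates 1, 2 and 3 were 0.29, 0.63 and -0.37, and those of the leukocyte list were 1.44, 1.57 and -0.30. Of 30 innate defence genes 1 rose, the protease inhibitor Slpi (2.49, SE 0.57, adjusted p = 0.0481), 1 fell, Lyz2, and 28 did not pass, with the same counts adjusted over the list alone. The median of that list was -0.08, against the upward direction of its test (camera adjusted p = 0.544, adjusted p = 0.638 with an estimated correlation).

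Leukocyte genes shifted higher in the adult arrays, carried by adult replicates 1 and 2. Of 26 genes 2 rose, the lymphocyte receptors Cd2 (4.39, SE 0.61, adjusted p = 0.0109) and Cd28 (4.11, SE 0.68, adjusted p = 0.0173), 0 fell and 24 did not pass, and adjusted over the list alone 10 were higher. The median was 1.13 (camera adjusted p = 4.27e-10, adjusted p = 0.315 with an estimated correlation). Taken as departures from each gene's mean over all arrays, the list's median was -0.99, -1.14 and -0.04 in E18 replicates 1, 2 and 3, and 1.44, 1.57 and -0.30 in adult replicates 1, 2 and 3. Of 23 macrophage genes 1 rose, Krt79 (2.27, SE 0.42, adjusted p = 0.024), a keratin listed as an alveolar macrophage marker, 0 fell and 22 did not pass, and adjusted over the list alone 2 were higher. The macrophage median was -0.51 and the mean -0.02, against an upward direction of the test (camera adjusted p = 0.666, adjusted p = 0.809 with an estimated correlation). That median depended on single arrays, at -0.05, -0.80 and -0.25 without adult replicates 1, 2 and 3. Csf1r, the macrophage growth factor receptor, was bright in both groups (14.41 ± 1.25 against 13.86 ± 0.09, adjusted p = 0.630).

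Cell division genes fell in the adult arrays. Of 48 genes 21 fell, 0 rose and 27 did not pass, and adjusted over the list alone 36 were lower. The median was -1.75 (camera adjusted p = 3.67e-15, adjusted p = 0.256 with an estimated correlation), with -2.05 in replicates 1 and 2 and -1.18 in replicate 3. The checkpoint kinase Bub1 (-3.18, SE 0.49, adjusted p = 0.0142), the mitotic kinase Plk1 (-2.84, SE 0.50, adjusted p = 0.0213), the spindle protein Prc1 (-2.75, SE 0.34, adjusted p = 0.00868) and the cell cycle kinase Cdk1 (-2.60, SE 0.39, adjusted p = 0.0126) fell most. The mesenchymal, endothelial and mesothelial lists fell in the same arrays, by medians of -3.76, -2.85 and -2.25. The proliferation marker Mki67, chosen after its values were seen, was lower by a difference of -1.79 (SE 0.31, adjusted p = 0.0214).

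Imprinted and fetal growth genes fell by more. Of 17 genes 11 fell, 0 rose and 6 did not pass, with 14 lower when adjusted over the list alone. The median was -3.40 (camera adjusted p = 6.57e-10, adjusted p = 0.273 with an estimated correlation), and -3.19 with values under the floor set to it. Grb10, an imprinted growth inhibitor, fell by 4.89 (SE 0.62, adjusted p = 0.00895), and the imprinted genes Mest and Peg3 fell by 4.84 (SE 0.69, adjusted p = 0.0112) and 4.83 (SE 0.96, adjusted p = 0.0304). Igf2, the fetal growth factor, chosen after its values were seen, had a difference of -4.47 (SE 0.50, adjusted p = 0.00617). The list's median was -4.0 in replicates 1 and 2 and -2.95 in replicate 3. The mesenchymal list moved the same way, with a median of -3.76.

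Among lung transcription factors 6 of 40 fell, 0 rose and 34 did not pass, with 7 lower when adjusted over the list alone. Besides Mycn, these included Sox11 (-3.40, SE 0.54, adjusted p = 0.0166), Nfib (-3.28, SE 0.67, adjusted p = 0.0335), a factor needed for lung maturation, and Sox4 (-2.27, SE 0.50, adjusted p = 0.0425). Other Sox4 probe sets above the floor changed less, at -0.57, -0.56, -1.25 and 0.05. Mycn and Sox11 are also in the fetal growth list. The median was -0.83 (camera adjusted p = 0.00681, adjusted p = 0.474 with an estimated correlation), with -1.37 in replicates 1 and 2 and -0.10 in replicate 3, and the list did not pass with all of a gene's probe sets averaged (-0.66, adjusted p = 0.0541). The general epithelial list had a like pattern, with -2.73 in replicates 1 and 2 and 0.57 in replicate 3, and the mesenchymal list was lower by a median of -3.76.

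Signalling lists of the FGF, Wnt and YAP pathways shifted lower in the adult arrays. Of 13 genes in the FGF list 3 fell, 0 rose and 10 did not pass, with 9 lower when adjusted over the list alone. They were the receptor Fgfr4 (-3.26, SE 0.46, adjusted p = 0.0112), the ligand Fgf18 (at least 4.55-fold lower, adjusted p = 0.0176) and Shh (-3.38, SE 0.78, adjusted p = 0.0499), a hedgehog ligand and not an FGF. The FGF list's median was -1.98 (camera adjusted p = 2.39e-05, adjusted p = 0.261 with an estimated correlation), with -2.78 in replicates 1 and 2 and -1.22 in replicate 3. Of 29 Wnt genes 7 fell, 0 rose and 22 did not pass, with 16 lower when adjusted over the list alone. They included the receptor Fzd2 (-4.73, SE 0.43, adjusted p = 0.0034), the secreted Wnt binders Sfrp2 (at least 6.26-fold lower, adjusted p = 0.0268) and Sfrp1 (-2.32, SE 0.33, adjusted p = 0.0116), and Lgr4 (-1.97, SE 0.35, adjusted p = 0.0227). Mesenchymal genes, with a median of -3.76, moved the same way as these lists. The Wnt median was -1.57 (camera adjusted p = 1.71e-06, adjusted p = 0.273 with an estimated correlation), with -1.80 in replicates 1 and 2 and -0.68 in replicate 3.

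Of 17 YAP and TEAD genes 5 fell, 0 rose and 12 did not pass, with 12 lower when adjusted over the list alone. Tgfb2 fell by 3.73 (SE 0.41, adjusted p = 0.00583), Ajuba by 3.24 (SE 0.59, adjusted p = 0.0238), Wwtr1, which encodes the YAP paralog TAZ, by 3.11 (SE 0.40, adjusted p = 0.00917) and Ccn2, a secreted YAP target, by 3.06 (SE 0.70, adjusted p = 0.0481). The median was -2.37 (camera adjusted p = 1.06e-05, adjusted p = 0.312 with an estimated correlation), with -2.82 in replicates 1 and 2 and -1.04 in replicate 3, and the epithelial and mesenchymal lists were lower in the same comparison by medians of -1.61 and -3.76. Notch and EGF receptor lists did not pass. Of 16 Notch genes 1 fell, the Notch ligand relative Dlk1 (-4.47, SE 0.55, adjusted p = 0.00868), which is imprinted and also in the fetal growth list, 0 rose and 15 did not pass, while the receptor Notch2 differed by 0.68 (adjusted p = 0.265). The Notch median was -0.81 (camera adjusted p = 0.455, adjusted p = 0.740 with an estimated correlation), and it was -0.38 without adult replicate 1, -0.53 without adult replicate 2, -0.28 with no filter and -0.37 with the 60th percentile filter. Of 22 EGF receptor and ERK genes 1 fell, the receptor Erbb3 (-2.37, SE 0.52, adjusted p = 0.0418), 0 rose and 21 did not pass, and the brightest other member, Phlda1, differed by -0.59 (adjusted p = 0.509). The EGF receptor median was -0.64 (camera adjusted p = 0.111, adjusted p = 0.638 with an estimated correlation), and it was -0.91 without adult replicate 3 (adjusted p = 0.0242) and -0.38 without adult replicate 1 (adjusted p = 0.318). Counts for both lists were the same adjusted over the list alone.

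Basement membrane genes were lower in the adult arrays, and so were genes of mesenchymal, endothelial and mesothelial cells. Of 30 basement membrane and matrix receptor genes 18 fell, 0 rose and 12 did not pass, with 24 lower when adjusted over the list alone. The median was -3.50 (camera adjusted p = 1.21e-16, adjusted p = 0.256 with an estimated correlation), with -3.62 in replicates 1 and 2 and -2.31 in replicate 3. The laminin chain Lama4 fell by 4.96 (SE 1.00, adjusted p = 0.0321), the integrin ligand Npnt by 4.79 (SE 0.42, adjusted p = 0.00303), the linker protein Nid1 by 4.44 (SE 0.80, adjusted p = 0.0229) and Col4a2 by 4.29 (SE 0.35, adjusted p = 0.00303). Markers of the other cell types were bright in the E18 arrays, at 12.36, 12.59 and 10.88 for Col1a1, 12.05, 11.98 and 9.63 for Cd34 and 11.01, 11.26 and 12.31 for Msln in E18 replicates 1, 2 and 3. E18 replicate 3 differed from E18 replicates 1 and 2 by medians of -1.55 for endothelial, -1.54 for mesothelial and -0.41 for mesenchymal genes. Whether RNA of non-epithelial cells in the E18 samples caused these decreases was not tested, and no purity data were given in the sources used here.

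Of 31 mesenchymal genes 21 fell, 0 rose and 10 did not pass, and adjusted over the list alone 26 were lower and 1 higher. Mfap4 and Mfap2, microfibril-associated proteins, fell by 7.55 (SE 1.23, adjusted p = 0.0171) and 5.31 (SE 0.74, adjusted p = 0.0109), and Cdh11 and Col1a1 belong here too. Mfap4 and Mfap2 were under the floor on 2 adult arrays each, and with those values set to the floor the differences were -5.81 and -4.53. The median was -3.76 (camera adjusted p = 3.76e-15, adjusted p = 0.273 with an estimated correlation), with -3.57 in replicates 1 and 2 and -4.02 in replicate 3. Of 28 endothelial genes 9 fell, 0 rose and 19 did not pass, with 23 lower when adjusted over the list alone. They included Cd34 (-4.63, SE 0.68, adjusted p = 0.0118), the receptor Tie1 (at least 4.88-fold lower, adjusted p = 0.0322), and the lymphatic markers Lyve1 (-3.51, SE 0.50, adjusted p = 0.0112) and Prox1 (at least 3.29-fold lower, adjusted p = 0.0319). The endothelial median was -2.85 (camera adjusted p = 2.75e-10, adjusted p = 0.312 with an estimated correlation), with -2.83 in replicates 1 and 2 and -2.68 in replicate 3.

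Of 12 mesothelial genes 4 fell, 0 rose and 8 did not pass, with 7 lower when adjusted over the list alone. Msln, or mesothelin, fell by 4.62 (SE 0.61, adjusted p = 0.00991), Upk3b by 4.09 (SE 0.75, adjusted p = 0.024), the peptide-processing enzyme Cpe by 4.07 (SE 0.80, adjusted p = 0.0299), and the transcription factor Wt1 was at least 2.72-fold lower (adjusted p = 0.0342). The median was -2.25 (camera adjusted p = 1.63e-05, adjusted p = 0.273 with an estimated correlation), with -2.94 in replicates 1 and 2 and -1.48 in replicate 3. With values under the floor set to it, the medians were -3.32 for basement membrane, -3.52 for mesenchymal, -2.33 for endothelial and -1.81 for mesothelial genes. Of 9 erythroid genes 0 rose, 0 fell and 9 did not pass, with 2 lower when adjusted over the list alone, a median of -0.69 (camera adjusted p = 0.155, adjusted p = 0.459 with an estimated correlation), or -0.38 with values under the floor set to it, and differences of -0.38 for Fech (adjusted p = 0.488) and -0.27 for Hbb-b2 (adjusted p = 0.803).

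General epithelial genes were lower in adult replicates 1 and 2 and not in adult replicate 3. Of 24 genes 3 fell, the junction genes Tjp1 (-3.14, SE 0.71, adjusted p = 0.0463), Cldn18 (-2.99, SE 0.37, adjusted p = 0.00857) and Cldn6 (at least 2.61-fold lower, adjusted p = 0.0452), 0 rose and 21 did not pass, with 4 lower when adjusted over the list alone. The median was -1.61 (camera adjusted p = 3.08e-04, adjusted p = 0.533 with an estimated correlation). It was -2.73 in replicates 1 and 2 and 0.57 in replicate 3, and it was -0.88 without adult replicate 1 and -2.72 without adult replicate 3. As departures from each gene's mean the list's medians were 0.76, 0.99 and 0.92 in E18 replicates 1, 2 and 3, and -1.83, -1.85 and 1.27 in adult replicates 1, 2 and 3. The leukocyte list had the opposite pattern among the adult arrays.

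**Figure D3:**
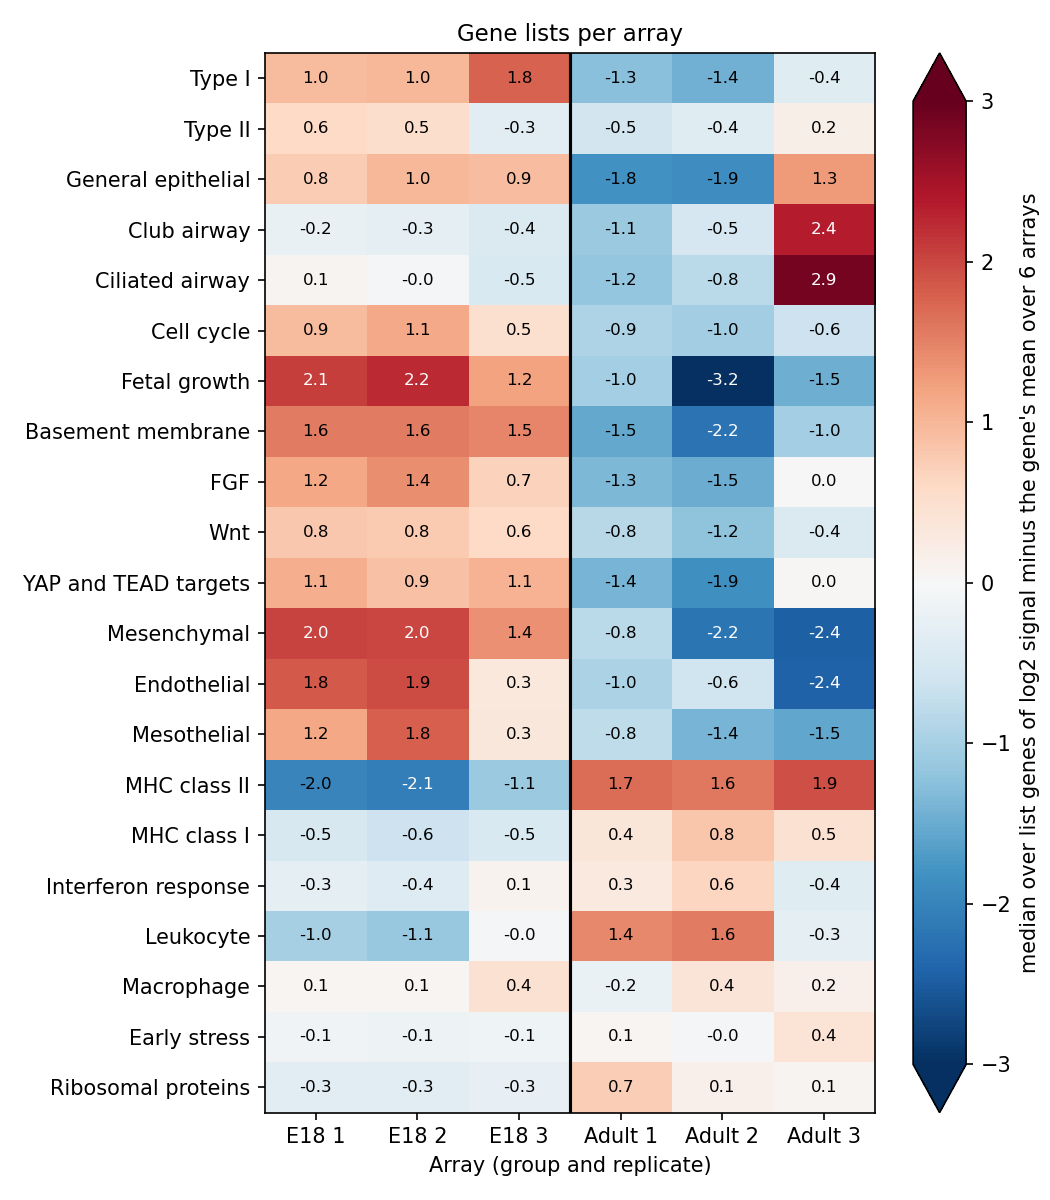
Heat map of the median log2 signal of 21 lists in each array, as departures from each gene's mean over the 6 arrays, with lists as rows and arrays as columns. Epithelial and airway lists were high in adult replicate 3 (1.27 for epithelial, 2.35 for club and 2.86 for ciliated genes), and the leukocyte list was high in adult replicates 1 and 2 (1.44 and 1.57).

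Airway cell genes were high in adult replicate 3, where the club list's median departure from each gene's mean was 2.35, against -1.12 and -0.51 in adult replicates 1 and 2. Of 11 club and secretory airway genes 1 rose, haptoglobin Hp (1.20, SE 0.25, adjusted p = 0.0377), which is made in many tissues, 0 fell and 10 did not pass, with the same counts adjusted over the list alone. The median was 1.19 (camera adjusted p = 0.0397, adjusted p = 0.629 with an estimated correlation). It was -0.43 in replicates 1 and 2 and 2.85 in replicate 3, and the list no longer passed without adult replicate 3 (-0.35, adjusted p = 0.899), without E18 replicate 3 (0.78, adjusted p = 0.102), after quantile normalization (1.15, adjusted p = 0.146) or with arrays centred on their medians (1.34, adjusted p = 0.0531). Scgb1a1, the main club cell secretory protein, differed by 1.62 (SE 0.48, adjusted p = 0.104). It passed with the poly-A batch as a block (adjusted p = 0.0181), in replicates 1 and 2 alone (adjusted p = 0.0217) and with arrays centred on their medians (adjusted p = 0.0471).

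Of 20 ciliated cell genes 0 passed in either direction, adjusted over all genes or adjusted over the list alone, and the median was 0.28 (camera adjusted p = 0.0930, adjusted p = 0.740 with an estimated correlation). Of these genes Tppp3 differed by 2.05 (SE 0.78, adjusted p = 0.179), or 2.99 without adult replicate 1 (adjusted p = 0.0236) and 1.25 without adult replicate 3 (adjusted p = 0.168). Dynlrb2 differed by 0.60 (adjusted p = 0.799), at 8.76, 9.83 and 13.8 in adult replicates 1, 2 and 3 against an E18 mean of 10.19. The ciliated median was -1.13 in replicates 1 and 2 (adjusted p = 0.0467) and 3.70 in replicate 3, opposite in sign. It was 1.15 without adult replicate 1 (adjusted p = 0.00148), 0.98 without adult replicate 2 (adjusted p = 0.00661), -0.90 without adult replicate 3 (adjusted p = 0.0727), 0.13 without E18 replicate 3 (adjusted p = 0.182), 0.46 with values under the floor set to it (adjusted p = 0.034) and 0.37 with 32 added before the log (adjusted p = 0.0392). Of 6 basal and neuroendocrine airway genes 1 fell, Krt15 (at least 7.05-fold lower, adjusted p = 0.0103), 0 rose and 5 did not pass, with the same counts adjusted over the list alone. Aqp3 differed by 0.22 (adjusted p = 0.877), at 6.21, 6.07 and 8.19 in adult replicates 1, 2 and 3 against an E18 mean of 6.61. The basal and neuroendocrine list's median was 0.09, or -0.20 without adult replicate 3, and its mean -0.70 (camera adjusted p = 0.761, adjusted p = 0.809 with an estimated correlation).

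Lipid synthesis, cholesterol synthesis and lysosome lists, which hold genes that serve surfactant production, did not pass. Of 29 lipid synthesis genes 1 fell, the desaturase Scd2 (-2.71, SE 0.38, adjusted p = 0.0111), 0 rose and 28 did not pass, with the same counts adjusted over the list alone, and the fatty acid elongase Elovl5 differed by 0.41 (adjusted p = 0.630). The median was -0.21 (camera adjusted p = 0.682, adjusted p = 0.775 with an estimated correlation), and -0.06 without adult replicate 1. Of 19 cholesterol synthesis genes 0 passed in either direction, adjusted over all genes or adjusted over the list alone, with differences of 0.54 for Hmgcs1 (adjusted p = 0.552) and 0.00 for Idi1 (adjusted p = 0.999). The list's median was 0.00 (camera adjusted p = 0.731, adjusted p = 0.775 with an estimated correlation). Of 27 lysosome and lamellar body genes 0 passed, also adjusted over the list alone, and Ctss and Npc2 differed by 0.67 (adjusted p = 0.307) and 0.56 (adjusted p = 0.380). The lysosome median was -0.10, or 0.08 without adult replicate 1, against an upward direction of its test (camera adjusted p = 0.377, adjusted p = 0.638 with an estimated correlation).

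Among other metabolic lists, the glycogen list shifted lower, and the respiratory chain and ribosomal protein lists shifted higher by small amounts that were not kept after quantile normalization. Of 17 glycogen genes 2 fell, Stbd1, a glycogen-binding protein (-3.75, SE 0.74, adjusted p = 0.0301), and Ppp1r3c, which targets a phosphatase to glycogen (-3.09, SE 0.64, adjusted p = 0.0338), 0 rose and 15 did not pass, with the same counts adjusted over the list alone. The median was -0.50 (camera adjusted p = 0.0163, adjusted p = 0.312 with an estimated correlation), with -0.85 in replicates 1 and 2 and -0.37 in replicate 3, and -0.79 with probe sets averaged. As departures from each gene's mean the glycogen list was -0.54, -0.36 and 0.07 in adult replicates 1, 2 and 3, where the epithelial list was -1.83, -1.85 and 1.27, and the epithelial and mesenchymal lists were lower by medians of -1.61 and -3.76. Of 18 glycolysis genes 0 passed, also adjusted over the list alone, the median was -0.35 (camera adjusted p = 0.666, adjusted p = 0.736 with an estimated correlation) and -0.22 without adult replicate 1, and Pgk1 and Ldha differed by 0.21 (adjusted p = 0.822) and -0.38 (adjusted p = 0.462). Pgk1 stood at 14.90, 13.88 and 13.21 in adult replicates 1, 2 and 3 against an E18 mean of 13.79. Of 41 respiratory chain genes 0 passed, also adjusted over the list alone, with differences of 0.49 for Cox5a (adjusted p = 0.437) and 0.72 for Ndufa1 (adjusted p = 0.306). Their median was 0.15 (camera adjusted p = 0.0177, adjusted p = 0.369 with an estimated correlation), 0.14 in replicates 1 and 2 and 0.19 in replicate 3. It was -0.06 after quantile normalization (adjusted p = 0.919), 0.22 without adult replicate 2 (adjusted p = 0.0905) and 0.07 without E18 replicate 3 (adjusted p = 0.118), and it was 0.33, 0.24 and 0.26 without adult replicate 3, E18 replicate 1 or E18 replicate 2. Of 27 ribosomal protein genes 0 passed, also adjusted over the list alone, with differences of 0.68 for Rps20 (adjusted p = 0.298) and 0.76 for Rpl38 (adjusted p = 0.275). The ribosomal median was 0.56 (camera adjusted p = 2.51e-08, adjusted p = 0.312 with an estimated correlation), 0.68 in replicates 1 and 2, 0.27 in replicate 3 and 0.06 after quantile normalization (adjusted p = 0.289). As departures from each gene's mean it was 0.74 in adult replicate 1, the array with a Gapdh 3' to 5' ratio of 24.6, and 0.14 and 0.08 in adult replicates 2 and 3.

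Of 18 ion and water transport genes 2 fell, the water channel Aqp1 (-4.23, SE 0.51, adjusted p = 0.00834), which is also abundant in endothelium, and Clic5, 0 rose and 16 did not pass, with 5 lower when adjusted over the list alone. The median was -0.75 (camera adjusted p = 0.0155, adjusted p = 0.524 with an estimated correlation), with -1.55 in replicates 1 and 2 and -0.12 in replicate 3, and the epithelial list had -2.73 and 0.57. The ion transport median was -0.62 without adult replicate 1 (adjusted p = 0.0565), -0.31 without adult replicate 2 (adjusted p = 0.0932), -1.65 without adult replicate 3 and -0.88 without E18 replicate 3 (adjusted p = 0.0545). Of 35 antioxidant and xenobiotic genes 2 fell, Gpx3 (-2.71, SE 0.49, adjusted p = 0.023) and Gstm5 (-2.15, SE 0.49, adjusted p = 0.0472), 0 rose and 33 did not pass, with the same counts adjusted over the list alone. The list nevertheless shifted higher, with a median of 0.33 (camera adjusted p = 0.0204, adjusted p = 0.533 with an estimated correlation), and it was -0.24 in replicates 1 and 2 and 1.26 in replicate 3. As departures from each gene's mean it was -0.34, -0.22 and 0.91 in adult replicates 1, 2 and 3, and the club and ciliated lists were also highest in adult replicate 3, at 2.35 and 2.86. The antioxidant median was -0.12 without adult replicate 3 (adjusted p = 0.494), 0.18 without E18 replicate 3 (adjusted p = 0.0890) and 0.54 without adult replicate 1. The antioxidant list also failed to pass after quantile normalization (0.06, adjusted p = 0.285), with probe sets averaged (0.09, adjusted p = 0.125) and without less specific probe sets (0.09, adjusted p = 0.0547).

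Of 31 immediate early and handling stress genes 2 rose, the heat shock genes Hspa1b (2.20, SE 0.31, adjusted p = 0.0109) and Hsph1 (1.43, SE 0.27, adjusted p = 0.0268), 0 fell and 29 did not pass, with 3 higher when adjusted over the list alone. The median was 0.33 (camera adjusted p = 0.00686, adjusted p = 0.312 with an estimated correlation), 0.24 in replicates 1 and 2 (adjusted p = 0.136) and 0.43 in replicate 3. It turned to -0.14 after quantile normalization (adjusted p = 0.910) and was 0.18 without adult replicate 3 (adjusted p = 0.123), 0.21 with probe sets averaged and 0.08 without less specific probe sets.

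Control probe sets set 1 adult array apart. The 3' to 5' signal ratio of Gapdh, which rises as RNA is shortened, was 24.6 in adult replicate 1 against 6.18 and 5.99 in adult replicates 2 and 3, and 4.77, 6.03 and 4.70 in E18 replicates 1, 2 and 3. For Actb it was 11.7, 1.55 and 1.43 in adult replicates 1, 2 and 3, and 1.52, 1.47 and 1.35 in the E18 arrays. In exact two-sided permutation tests of 3 arrays against 3, in which p cannot be lower than 0.1, p was 0.2 for Gapdh, 0.4 for Actb, 0.5 for the poly-A spike-ins, 0.1 for the hybridization spike-ins and 0.4 for the median signal. The poly-A spike-ins averaged 7.42, 6.87 and 13.7 in E18 replicates 1, 2 and 3 and 8.30, 9.61 and 14.2 in adult replicates 1, 2 and 3.

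**Figure D4:**
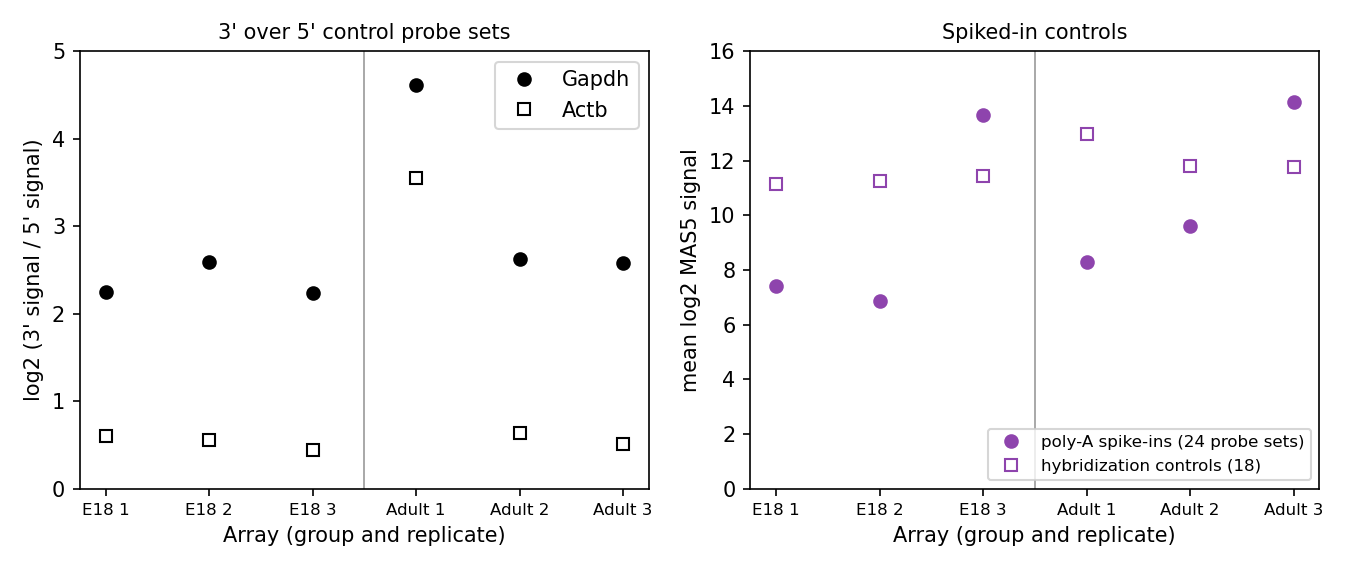
Control probe sets per array, on log2 scales, with the 3' over 5' difference of Gapdh and Actb and the mean signals of poly-A and hybridization spike-ins. Adult replicate 1 had the highest 3' over 5' differences, and replicate 3 of each group had the highest poly-A signals, 13.7 and 14.2.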

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

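Apart from the counts over other splits of the arrays, which were planned, all tests in this part were chosen after the results were seen. The poly-A spike-ins, added to RNA before labelling and read by 24 control probe sets outside the comparison, gave a signal that set the third replicates apart. Their median log2 signal was 5.75 higher in adult replicate 3 than in adult replicates 1 and 2, and 6.87 higher in E18 replicate 3 than in E18 replicates 1 and 2. The same differences for the hybridization spike-ins, added later, were -0.58 and 0.25. With 10 splits of 6 arrays into 3 and 3, a share under 0.05 cannot be reached. The real split gave 798 genes, at any size or at least 2-fold, and 23 lists, and was the 1 split of 10 with so many. The highest of the other splits gave 0 genes and 18 lists. Lists thus passed at the preset correlation under other groupings too. Each other split mixes the groups unevenly and keeps part of their difference, so these counts give no rate for unshifted lists.

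Lyz2 was lower in the adult arrays, by a difference of -2.86, although the adult cells were sorted for Lyz2. Fewer type II cells in the adult samples would lower the other type II markers too, if their levels per cell were alike in both groups. The other type II markers, read without the sort genes and without Lyz1, had a median difference of -0.34, against -2.86 for Lyz2. The whole type II list had a median of -0.44. The 95% bootstrap interval of that median, -0.74 to -0.13, resampled genes and not arrays, so it leaves out the spread between replicates. The type II list had a median of -0.95 in the replicates with low poly-A signal and 0.52 in those with high poly-A signal. Lyz2 fell by more in both, at -2.73 and -3.14. These values do not decide whether fewer type II cells contributed, since type II genes may themselves differ with age. The macrophage list had a median of -0.51 (-0.85 to 0.55, also over genes), which was -0.05 to -0.80 with 1 adult array omitted, so its genes as a group fell less than Lyz2. That does not decide whether fewer macrophages contributed, since macrophage genes may themselves differ with age. Loss of 5' sequence in adult replicate 1 is argued against by a Lyz2 difference of -2.94 without that array (adjusted p = 0.00315). Age and population differ together in this design and stay open as untested explanations. How Lyz2 was marked for sorting was not given in the sources used here, so an altered Lyz2 allele in the sorted adult cells was also not tested.

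Leukocyte transcripts were higher in the adult arrays, and a candidate explanation is RNA of lymphoid cells in the sorted adult samples. Lists of T, B, NK and plasma cell genes, written after the leukocyte result, were read without genes of the fixed lists or named by the fixed rule and with values under the floor set to it. Their median differences were at least 2.15. Igha stood at 14.49 and Jchain at 14.35 in the adult arrays, although a sort for EpCAM should remove lymphoid cells. The lists held only tested genes, and a gene under the floor in all E18 arrays was tested only if it reached the floor in all adult arrays. That rule favours positive medians, so they do not decide whether such RNA was the source. In adult replicate 3 the MHC class II list differed from adult replicates 1 and 2 by 0.41, the B cell list by -3.01 and the dendritic cell list by 2.55. This contrast rests on 1 array and decides nothing about B cells or dendritic cells as the whole source of the MHC class II signal. Those cells, a mixture of sources, and expression by adult type II cells themselves stay open.

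Adult replicate 3 stood apart from adult replicates 1 and 2 in epithelial and airway genes. For the general epithelial list, adult replicates 1 and 2 lay below the E18 arrays. As departures from each gene's mean, its medians were -1.83, -1.85 and 1.27 in adult replicates 1, 2 and 3, and 0.76, 0.99 and 0.92 in E18 replicates 1, 2 and 3. Across genes, the departures of adult and E18 replicate 3 from their groups had a correlation of -0.058. This argues against a technical batch that shifted genes alike in both replicate 3 arrays as the cause. A batch that acted differently on each group would not show in this correlation. Since replicate 3 of both groups had the higher poly-A signal, such a batch stays open. A lower share of leukocytes alone would raise purely epithelial lists alike, and the medians of ciliated and type II genes differed by 3.50. The type II list holds genes, such as Lyz2, that leukocytes may also express, so this gap does not decide it. RNA of club and ciliated airway cells may contribute, since 26 ciliated and 12 club cell genes outside the lists that showed the pattern were higher there by medians of 3.95 and 4.93, although the gate for Lyz2 should remove such cells and Scgb1a1 was bright in every adult array, at 13.74, 13.54 and 15.03 in adult replicates 1, 2 and 3. A difference between the animals was not tested.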

How the results depend on the processing

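The poly-A batch as a block, replicates 1 and 2 alone, replicate 3 alone and E18 replicates 1 and 2 averaged were settings chosen after seeing the data. The count of changed genes was 798 and stayed between 672 and 929 under the other scalings, filters, floors, variance priors and probe set choices and with the poly-A batch as a block, and it was 1112 probe sets when all were tested. It moved to 2996 in replicates 1 and 2 alone (2979 at least 2-fold) and to 63, at any size or at least 2-fold, with E18 replicates 1 and 2 averaged, a setting with fewer samples. Omitting 1 replicate gave 66 to 2770 genes (66 to 2758 at least 2-fold). With a replicate block 492 genes changed, at any size or at least 2-fold, and 430 of these were among the 798, while 23 lists shifted. Across genes, deviations of same-numbered arrays correlated at 0.036, -0.140 and -0.058 and no array correlated best with its own number, although the poly-A signal set the third replicates of both groups apart. Under these settings 19 to 24 lists shifted, of 35 tested or of 33 with the higher filter and 34 with probe sets averaged, with 13 of 35 in fry and 0 of 35 with an estimated correlation. The stress list turned to -0.14 after quantile normalization, and in replicate 3 alone the interferon list was -0.43, the leukocyte list -0.13 and the epithelial list 0.57, and the cause was not tested. Over the other settings, 1389 of 1554 values of named genes kept their side of the threshold, 160 lost the call, 5 gained it and 0 reversed. With 1 replicate omitted these counts were 437, 232, 3 and 0 of 672. A change of sign was counted as a reversal only for genes and lists that had passed, so those that had not passed could change sign and count as kept. The estimated correlation ended 23 list calls and fry 10. Apart from these set tests 504 of 522 list values kept their side of the threshold, 11 lost the call, 6 gained it and 1 reversed in the direction of its test. With 1 replicate omitted 195 of 210 list values kept their side, 11 lost the call and 4 gained it. In replicate 3 alone 71 of 112 named genes and 18 of 35 lists stayed within the replicate spread of their value. Signal near the floor limits 144 of the 798 genes to a lower bound on their change.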

Other observations

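The single test in this part, of Y-linked genes, was chosen after the result was seen, as were the lineage gene lists described first. Lists of immune lineages, compiled after the leukocyte result, showed genes of several cell types higher in the adult arrays. Median differences were 4.11 for 7 plasma cell genes, 4.07 for 8 T cell genes, 3.96 for 8 dendritic cell genes, 3.91 for 8 natural killer cell genes and 3.77 for 9 B cell genes, of which 6, 5, 5, 6 and 2 passed as higher. With values under the floor set to it these medians were 4.11, 3.03, 3.73, 3.82 and 2.59, and the lists hold genes whose increase was already known, such as Jchain, Igha, Klrd1, Icos, Cd2 and Cd28. The lists also hold only tested genes, so a gene under the floor in all E18 arrays entered only if it reached the floor in all adult arrays. Mzb1, a chaperone of antibody-secreting cells, rose by 4.11 (adjusted p = 0.00303), the B cell coactivator Pou2af1 by 4.51 (adjusted p = 0.0111), the migration receptor Ccr7 by 5.51 (adjusted p = 0.00868), and the chemokine Ccl22 by 5.04 (adjusted p = 0.0341), and Cd207, or langerin, was at least 10.3-fold higher (adjusted p = 0.0379). The 10 neutrophil genes had a median of 1.12, and 0 of them passed. The leukocyte list shares 3 of the B cell, 3 of the neutrophil, 2 of the NK cell and 4 of the T cell genes.

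Adult arrays differed in which immune genes they carried. Adult replicate 3 differed from adult replicates 1 and 2 by medians of -3.67 for neutrophil, -3.29 for natural killer, -3.01 for B cell and -2.42 for T cell genes, by 0.31 for plasma cell genes and by 2.55 for dendritic cell genes. S100a8, a neutrophil gene, stood at 16.01, 14.98 and 11.22 in adult replicates 1, 2 and 3 and at 13.9, 13.7 and 14.8 in the E18 arrays. The differences between adult arrays were not tested, since each rests on 1 array.

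The Y-linked genes Eif2s3y and Kdm5d were lower in all adult arrays than in any E18 array, by a median of -2.90 over these 2 genes with values under the floor set to it. Eif2s3y, under the floor in 2 adult arrays, differed by -3.90 on that scale, and Kdm5d, under the floor in all adult arrays, was at least 3.73-fold lower (adjusted p = 0.0278). Before flooring, Eif2s3y stood at 9.92, 9.85 and 10.13 in E18 replicates 1, 2 and 3. In adult replicates 1, 2 and 3 it stood at 6.75, 1.32 and 3.84. Fewer male animals behind the adult samples could lower both genes. The -2.90 does not decide it, since with all adult values at the floor Kdm5d could not pass -1.90. The sex of the animals was not given in the sources used here, so sex may differ between the groups along with age and population.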
